A study of Homo sapiens with 13 samples.

How the data were processed

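RNA was measured in 13 libraries of U2OS cells, as total RNA depleted of ribosomal RNA and as RNA bound to eIF4G after immunoprecipitation (IP), with single-end reads, per the labels' protocols. Groups were taken from the sample labels: IP with control siRNA (3 libraries), CDK12 siRNA (2) and control siRNA with rapamycin (2), and total RNA of the same conditions (2 each). Replicate numbers are those of the labels. The rapamycin libraries share a date code that no other library has.

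The deposited values are FPKM per gene, made by the authors with HOMER's repeat and gene counting program, per the file headers, over whole gene bodies of hg19 (median length 15088 bp), so introns count. STAR 2.4.0k and FastQC are named per the submitters' processing notes. The strand setting, the read filters and the annotation release are not given in the sources used here. The deposited group means and differences between them are log2 values of FPKM + 1, which the authors computed per gene, and the authors' deposited table also marks genes with TRUE or FALSE calls of lost binding and changed expression. The table holds 26454 genes, 19258 of them protein-coding. In it, 28 symbols turned into dates by a spreadsheet were repaired from the gene name in the annotation column. There, 2 symbols are repeated, 841 genes have more than 1 genomic copy, and 3 emptied lines were left out. Every value column of the table was read.

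FPKM values of low genes were whole multiples of 1 read in 100% of the values used (tolerance 0.02 reads), which gave depths of 12.9 to 30.7 (in units of 1e6 tags) per library. FPKM are not counts, so genes were tested on log2(FPKM + 1), after division by median-ratio factors between 0.869 and 1.23, with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3. Genes with FPKM of at least 1 in at least 2 libraries were kept, 9908 in all. The 6 groups entered 1 fit without covariates, which gave 9.22 degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each of 8 contrasts with a threshold of 0.05. The contrasts are each treatment against control in the IP and in total RNA, the interaction of fraction and treatment for each, IP against total RNA in control cells, and the difference of both interactions. Fold thresholds are 2-fold. Files were read with the R package data.table in version 1.17.8, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

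Before the data were examined, 34 gene lists were fixed, and the tests, the alternatives, the groups and the rule for named genes were written down. The lists cover ribosomal proteins, other oligopyrimidine mRNAs, translation initiation, the mTOR pathway, CDK12 and polymerase II kinases, homologous recombination, the DNA damage checkpoint, centromere, centrosome, mitotic motors and kinases, cohesin and condensin, the anaphase-promoting complex, DNA replication, oxidative phosphorylation, the mitochondrial ribosome, mitochondrially encoded genes, nuclear noncoding RNA, small nucleolar RNA hosts, histones, p53 targets, ATF4 targets, cholesterol, glycolysis, lysosome and autophagy, endoplasmic reticulum chaperones, extracellular matrix, immediate early genes, interferon, heat shock, splicing, cytoskeleton, and haematopoietic, epithelial and mesenchymal markers. Lists with at least 5 tested members, 32 of them, were tested against all other tested genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Their medians are given relative to the median of all tested genes. Of 87 list calls over the 8 contrasts, 7 held with an estimated correlation, those of mitotic genes in the IP after CDK12 siRNA, and of mitotic, DNA replication, centromere, centrosome, homologous recombination and checkpoint genes in total RNA after CDK12 siRNA.

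Named genes are 8 fixed genes (CDK12, CDK13, CCNK, MTOR, EIF4G1, EIF4E, EIF4EBP1 and CHEK1), genes among the 10 largest rises and falls past the threshold in each IP contrast and each interaction and the 5 largest in the others, with a mean FPKM of at least 5 in a compared group and treated libraries all on one side of the controls, and up to 4 members with the smallest p of each list that passed. Overlaps of calls and correlations between treatments were set against 100 simulations of unchanged groups with the same controls. Intervals are 95% bootstrap intervals of medians over genes (2000 draws), and cover sampling of genes only. Replicates were compared over genes with at least 20 reads by chi-square, and no pair agreed within counting noise.

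The fit was tested on simulated data with the spread of each real group, in 5 draws over 8887 to 8917 genes with 200 changed genes each. For the IP after CDK12 siRNA it found 56.2%, 86.0% and 95.6% of genes changed 1.5-fold, 2-fold and 4-fold. It also called 1.83% of unchanged genes, since this pair of libraries varied more than the others (dispersion 0.0261 against 0.00123 to 0.0127). Of its calls outside the ribosomal protein list, which was shifted as a whole, 53.1% fell on unchanged genes. That share was 6.49% with library weights, 6.34% with the compared groups alone and 0.978% for genes called in all 3 fits. For the interaction with CDK12 siRNA it was 15.8%, and 3.15% for all 3 fits. These shares depend on the number of changed genes simulated, so they do not carry over to the calls in the real data. In the contrasts simulated with no change at all, of 44499 gene tests the pooled fit called 12 in total RNA after CDK12 siRNA, 15 in total RNA with rapamycin and 5 in the rapamycin interaction. The ribosomal protein list, shifted by -1, was called in 5 of 5 draws. In the IP after CDK12 siRNA camera called 0 of 155 tests of other lists. Genes were simulated independently of each other, so this cannot show how often correlated genes give false list calls. The design was kept as fixed, and the text leads with genes called in all 3 fits for the IP after CDK12 siRNA.

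Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, FPKM without scaling, quantile normalization, the compared groups alone, library weights, the replicate number as a block, each library left out in turn, camera with estimated correlations and limma's fry. Restriction to protein-coding genes, restriction to genes that overlap no other gene, removal of the trend with gene length (loess, span 0.5) and the requirement of 3 fits were chosen after seeing the data. Genes marked in the authors' deposited table were counted against the interaction calls without a test, and the gene lists among those in both narrower sets of that table were tested by Fisher's exact test.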

Results

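RNA bound to eIF4G, the scaffold protein of the complex that brings capped mRNAs to the ribosome, was collected by immunoprecipitation (IP) from U2OS cells, a human osteosarcoma line, and sequenced beside total RNA. The cells received a control siRNA, an siRNA against CDK12, a kinase that phosphorylates RNA polymerase II, or the control siRNA with rapamycin, an inhibitor of the growth-regulating kinase complex mTORC1. The IP gave 3 control, 2 CDK12 siRNA and 2 rapamycin libraries, and total RNA gave 2 libraries of each. siRNA lasted 48 h, and rapamycin was present at 50 ng/ml for 24 h. Depths are in units of 1e6 tags. The control IP libraries held 12.9, 23.0 and 18.3, the CDK12 siRNA IP libraries 17.5 and 21.5, and the rapamycin IP libraries 19.9 and 18.9. The total RNA libraries held 18.2 and 21.7 in control cells, 21.3 and 17.2 after CDK12 siRNA, and 21.5 and 30.7 with rapamycin. Levels are mean deposited FPKM ± SD over gene bodies, introns included, with n = 3 in the control IP and n = 2 in every other group. Changes are log2 ratios ± SE from limma on scaled log2(FPKM + 1), a scale that understates changes of genes with low values, and 9908 genes were tested. Medians of gene lists are relative to the median of all tested genes. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. The rapamycin libraries carry a different date code from all others, so date and rapamycin cannot be told apart in any comparison of rapamycin with control. The strand setting of the counting is not given in the sources used here, so values of genes that overlap another gene are uncertain. Among the genes named this concerns ATP5B, EIF4E2, EIF4G1, FKBP1A, HSPD1, HSPE1, MMP3, MTOR, NPC1, PDIA6, SLC7A11, SQSTM1, TCP1, TNFRSF10B and WIPI1.

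The libraries separated first by fraction. Principal component 1 held 70.2% of the variance and placed the control IP between -68.8 and -61.3 and control total RNA at 50.8 and 51.0. The rapamycin IP lay between them at -6.87 and 8.68. Across genes, which are not independent replicates, the mean rapamycin IP correlated at r = 0.94 with rapamycin total RNA and at 0.83 with the control IP. The CDK12 siRNA IP correlated at 0.95 with the control IP. Tags inside gene bodies made up 97.0 ± 0.531% of the control IP, 97.9 ± 0.251% of the CDK12 siRNA IP and 92.4 ± 1.36% of the rapamycin IP. In total RNA they made up 83.2 ± 0.295% in control cells, 81.0 ± 0.246% after CDK12 siRNA and 87.2 ± 0.804% with rapamycin. MYO1D, an unconventional myosin on chromosome 17, took 5.50% and 6.31% of all tags in the rapamycin IP libraries. It took 0.341% and 0.817% in the CDK12 siRNA IP libraries, and between 0.0147% and 0.0765% in the other libraries. The pair of CDK12 siRNA IP libraries differed more from each other than any other replicate pair, with a chi-square per degree of freedom of 57.7 against 3.53 to 22.4 elsewhere.

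CDK12 (hg19 chromosome 17, 37617764 to 37690818) fell in total RNA after its siRNA to 42.1% of control. Its total RNA level was 1.64 and 1.72 FPKM in the control libraries, 0.706 and 0.707 after CDK12 siRNA, and 1.25 and 1.29 with rapamycin. In the IP it measured 0.497, 0.532 and 0.535 FPKM in control cells, 0.493 and 0.338 after CDK12 siRNA, and 0.916 and 0.953 with rapamycin. The fall in total RNA after siRNA was -0.55 ± 0.05 (adjusted p = 4.52e-05). Rapamycin total RNA was also lower, at -0.37 ± 0.05 (adjusted p = 0.0009). In the CDK12 siRNA IP the change was -0.17 ± 0.05 (adjusted p = 0.0264) with all groups pooled. That call was lost without scaling (-0.11), with the length trend removed (-0.10), with quantile normalization (-0.16), with library weights (-0.17) and with the compared groups alone (-0.17). It was also lost without IP CDK12 siRNA replicate 3 (-0.10) or control IP replicate 2 (-0.17) or 3 (-0.17). CDK13, the closest relative of CDK12, rose in total RNA by 0.46 ± 0.05 (adjusted p = 0.000119). CCNK, the cyclin partner of both kinases, stayed under the filter at 0.568 ± 0.0396 FPKM in control and 0.751 ± 0.0375 FPKM in CDK12 siRNA total RNA.

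**Figure D1:**
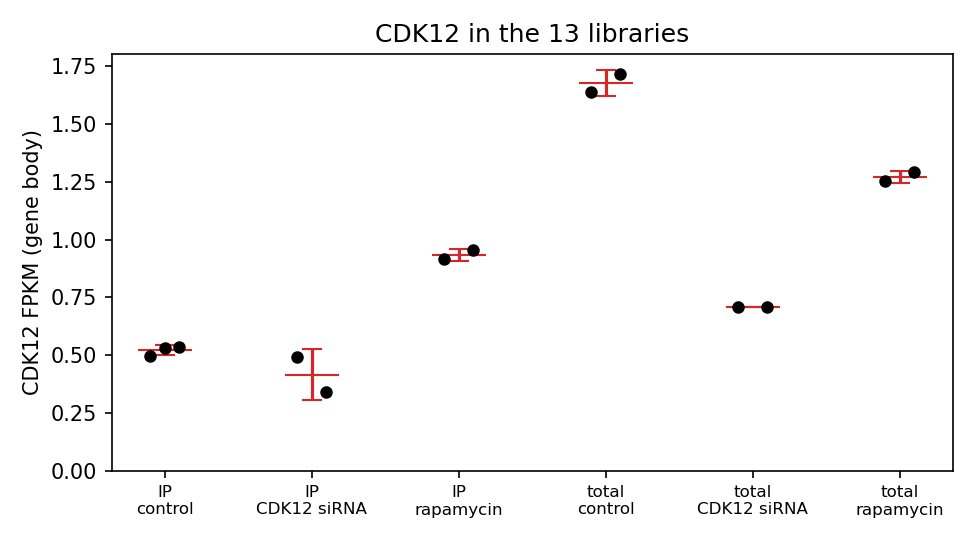
CDK12 FPKM over the gene body in each of the 13 libraries (points), with the mean and SD of each group in red. Total RNA held 1.68 ± 0.0544 FPKM in control cells and 0.707 ± 0.000707 after CDK12 siRNA, and the control IP held 0.521 ± 0.0211.

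The IP was first set against total RNA in control cells. No mock IP is given, so binding cannot be told from background. mRNAs of the ribosome, the mitochondrial ribosome and oxidative phosphorylation, which makes ATP in mitochondria, stood high in the IP. Their list calls were lost, at adjusted p = 0.606, 0.585 and 0.585 with an estimated correlation. RPL26, a protein of the large ribosomal subunit, measured 1031 ± 68.3 FPKM in the IP and 34.7 ± 0.297 in total RNA, a difference of 5.05 ± 0.25 (adjusted p = 1.16e-07). DBI, an acyl-CoA binding protein, was higher by 4.71 ± 0.15, and RPS6, of the small ribosomal subunit, by 4.08 ± 0.16. The complex I subunits NDUFS5 and NDUFB3 were higher by 4.52 ± 0.18 and 3.93 ± 0.12, and the mitochondrial ribosomal protein MRPL32 by 4.06 ± 0.15. Ribosomal protein genes had a median of 1.91 (camera adjusted p = 3.9e-06, adjusted p = 0.606 with an estimated correlation). Of these, 69 of 77 were higher in the IP and 1 lower, or 69 and 1 adjusted over the list alone. Oxidative phosphorylation genes had a median of 1.80 (camera adjusted p = 6.03e-09, adjusted p = 0.585 with an estimated correlation). Among them 71 of 71 were higher, or 71 adjusted over the list alone. Mitochondrial ribosome genes had a median of 1.67 (camera adjusted p = 6.03e-09, adjusted p = 0.585 with an estimated correlation). Of their members 71 of 75 were higher and 1 lower, or 71 and 1 adjusted over the list alone.

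Replication-dependent histones, whose mRNAs carry no poly(A) tail, had a median of 2.08 (camera adjusted p = 0.000531, adjusted p = 0.606 with an estimated correlation). In this list 34 of 35 were higher in the IP, or 34 adjusted over the list alone. HIST1H2BC stood at 3.96 ± 0.21. Heat shock genes, which encode chaperones of the cytosol and mitochondria, had a median of 1.75 (camera adjusted p = 0.00185, adjusted p = 0.585 with an estimated correlation). Of these, 18 of 21 were higher in the IP, or 18 adjusted over the list alone. The mitochondrial co-chaperone HSPE1 stood at 3.81 ± 0.18. Chaperones of the endoplasmic reticulum had a median of 0.96 (camera adjusted p = 0.002, adjusted p = 0.585 with an estimated correlation). Among them 27 of 30 were higher in the IP and 1 lower, or 27 and 1 adjusted over the list alone. Translation initiation factors had a median of 0.82 (camera adjusted p = 0.0123, adjusted p = 0.585 with an estimated correlation). Of their members 23 of 27 were higher in the IP and 3 lower, or 23 and 3 adjusted over the list alone. EIF3E stood at 3.03 ± 0.15 and the cap-binding EIF4E2 at 2.00 ± 0.09. Other mRNAs with the oligopyrimidine motif that mTOR regulates had a median of 0.66 (camera adjusted p = 0.00373, adjusted p = 0.585 with an estimated correlation). In this list 21 of 24 were higher in the IP, or 21 adjusted over the list alone. ATF4, the transcription factor of the amino acid response, stood at 2.77 ± 0.12. Cohesin and condensin genes had a median of -0.59 (camera adjusted p = 0.0142, adjusted p = 0.585 with an estimated correlation). Of these, 11 of 21 were lower and 7 were higher, or 11 and 7 adjusted over the list alone. NIPBL, which loads cohesin, differed by -1.01 ± 0.06 and the proliferation marker MKI67 by -2.46 ± 0.12. Genes of homologous recombination, a DNA repair pathway, had a median of -0.53 (camera adjusted p = 0.0123, adjusted p = 0.585 with an estimated correlation). Among them 11 of 21 were lower and 6 were higher, or 11 and 6 adjusted over the list alone. BRCA2 differed by -0.74 ± 0.04.

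In all, 7972 genes differed between IP and total RNA, 5355 higher in the IP and 2617 lower, around a median of 0.35, and 3161 differed at least 2-fold. Without scaling the split was 4888 higher and 3012 lower (median 0.22), and with quantile normalization 3881 and 3752 (median 0.03). Quantile normalization ended the calls of ribosomal proteins (0.41), histones (0.30), heat shock genes (0.15) and endoplasmic reticulum chaperones (0.22), and turned initiation factors to -0.01 and the oligopyrimidine mRNAs to -0.37. The filter at a mean FPKM of 5 ended the calls of ribosomal proteins (0.80), oxidative phosphorylation (1.07), histones (0.81) and heat shock genes (0.46), and turned endoplasmic reticulum chaperones to -0.22, initiation factors to -0.18 and the oligopyrimidine mRNAs to -0.27. Removing the trend with gene length (rho across genes -0.33) ended the calls of cohesin (-0.09) and homologous recombination genes (-0.24), and no filter that of cohesin (-0.34). Among genes that overlap no other, initiation factors (0.74) and the oligopyrimidine mRNAs (0.44) lost their calls.

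Total RNA after CDK12 siRNA shows which transcripts changed in the cells themselves. Histone and cell division genes fell, and the p53 target CDKN1A and the growth regulator MYC rose. The mitotic list call held, and the histone call was lost, at adjusted p = 0.211 with an estimated correlation. The linker histone gene HIST1H1E dropped from 232 ± 8.60 to 21.6 ± 1.78 FPKM (-3.16 ± 0.13). TOP2A, the topoisomerase that untangles replicated DNA, dropped from 19.3 ± 0.0417 to 1.32 ± 0.0219 FPKM (-2.99 ± 0.08, adjusted p = 1.46e-07). RRM2, a subunit of the enzyme that makes DNA precursors, dropped from 18.1 ± 0.220 to 1.38 ± 0.131 FPKM (-2.87 ± 0.13). CDKN1A, the cell cycle inhibitor p21, rose from 6.82 ± 0.839 to 27.8 ± 0.0523 FPKM (2.09 ± 0.16, adjusted p = 1.01e-05), and MYC from 6.26 ± 0.214 to 14.1 ± 1.22 FPKM (1.26 ± 0.10).

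Replication-dependent histone genes had a median of -3.08 (camera adjusted p = 1.43e-17, adjusted p = 0.211 with an estimated correlation). Of their members 31 of 35 fell, or 32 adjusted over the list alone. Histone genes are near copies of each other, so reads may be shared between members. Mitotic motors and kinases had a median of -1.46 (camera adjusted p = 5.71e-29, adjusted p = 0.016 with an estimated correlation). In this list 43 of 43 fell, or 43 adjusted over the list alone. ASPM, a spindle pole protein, changed by -1.97 ± 0.07. DNA replication genes had a median of -0.82 (camera adjusted p = 6.9e-20, adjusted p = 0.0257 with an estimated correlation). Of these, 41 of 45 fell, or 41 adjusted over the list alone. Centromere and kinetochore genes had a median of -0.84 (camera adjusted p = 1.67e-18, adjusted p = 0.036 with an estimated correlation). Among them 39 of 45 fell and 1 rose, or 41 and 1 adjusted over the list alone. ZWINT, a kinetochore protein, changed by -2.58 ± 0.10. Homologous recombination genes had a median of -0.59 (camera adjusted p = 4.47e-07, adjusted p = 0.036 with an estimated correlation). Of their members 16 of 21 fell and 2 rose, or 16 and 2 adjusted over the list alone. BRCA1 changed by -0.92 ± 0.05, from 1.21 ± 0.0665 to 0.132 ± 0.0198 FPKM, and its partner helicase BRIP1 by -1.11 ± 0.06. DNA damage checkpoint genes had a median of -0.41 (camera adjusted p = 5.42e-05, adjusted p = 0.036 with an estimated correlation). In this list 11 of 19 fell, or 12 adjusted over the list alone. The checkpoint kinase CHEK1 changed by -0.39 ± 0.07. Centrosome genes had a median of -0.42 (camera adjusted p = 4.29e-06, adjusted p = 0.0257 with an estimated correlation). Of these, 22 of 36 fell and 2 rose, or 24 and 2 adjusted over the list alone. Cohesin and condensin genes had a median of -0.52 (camera adjusted p = 5.42e-05, adjusted p = 0.211 with an estimated correlation). Among them 13 of 21 fell and 2 rose, or 13 and 3 adjusted over the list alone. Cytoskeleton genes had a median of -0.23 (camera adjusted p = 0.00506, adjusted p = 0.501 with an estimated correlation). Of their members 13 of 30 fell and 1 rose, or 13 and 2 adjusted over the list alone. The actin-binding tropomyosin TPM1 changed by -1.19 ± 0.13.

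Targets of p53, the tumour suppressor that responds to DNA damage, had a median of 0.56 (camera adjusted p = 5.01e-05, adjusted p = 0.211 with an estimated correlation). In this list 17 of 25 rose and 3 fell, or 18 and 4 adjusted over the list alone. The death receptor TNFRSF10B rose by 0.86 ± 0.06. Lysosome and autophagy genes had a median of 0.28 (camera adjusted p = 0.00155, adjusted p = 0.305 with an estimated correlation). Of these, 19 of 34 rose and 3 fell, or 20 and 3 adjusted over the list alone. The cargo receptor SQSTM1 rose by 1.14 ± 0.11 and the cholesterol exporter NPC1 by 0.86 ± 0.05. Immediate early genes, which growth factors switch on within minutes, had a median of 0.43 (camera adjusted p = 0.0109, adjusted p = 0.305 with an estimated correlation). Among them 9 of 17 rose, or 9 adjusted over the list alone. FOSL1 rose by 1.36 ± 0.14. mTOR pathway genes had a median of 0.18 (camera adjusted p = 0.0342, adjusted p = 0.262 with an estimated correlation). Of their members 10 of 25 rose and 1 fell, or 10 and 1 adjusted over the list alone. FKBP1A, the protein rapamycin binds, rose by 0.89 ± 0.11. The mTOR pathway call was lost without total control replicate 2, at 0.20. The largest rises included the matrix protease MMP3, from 0.147 ± 0.0177 to 13.8 ± 0.227 FPKM (3.87 ± 0.59), whose gene overlaps the WTAPP1 pseudogene, and the noncoding RNA UCA1 (2.95 ± 0.21). Ribosomal protein genes did not pass as a list (median -0.23, camera adjusted p = 0.0612). They passed with the compared groups alone (-0.23), library weights (-0.23), quantile normalization (-0.25), the replicate number as a block (-0.23) and no filter (-0.21). They also passed without CDK12 siRNA IP replicate 2 (-0.23) or 3 (-0.23) or rapamycin IP replicate 1 (-0.22) or 2 (-0.22). The CDK12 complex and polymerase II kinase genes did not pass (median 0.32, camera adjusted p = 0.0651).

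In all, 4240 genes changed, 2308 up and 1932 down, and 450 at least 2-fold, 164 up and 286 down. Without scaling the split turned to 1276 up and 2754 down around a median of -0.10, and the count was 2763 or 2745 without total CDK12 siRNA replicate 1 or 2. The filter at a mean FPKM of 5 ended the calls of lysosome (0.34) and mTOR pathway genes (0.17).

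In the IP after CDK12 siRNA the mitotic and histone lists fell and the lysosome list rose. In all 3 fits 40 of 43, 15 of 35 and 11 of 34 members did so. The mitotic call held, and the histone and lysosome calls were lost, at adjusted p = 0.234 and 0.0832 with an estimated correlation. TPX2, which nucleates spindle microtubules, dropped from 4.16 ± 0.108 to 1.39 ± 0.196 FPKM (-1.26 ± 0.05, adjusted p = 8.91e-06). The kinesin KIF2C dropped from 9.24 ± 0.394 to 3.89 ± 0.0255 FPKM (-1.23 ± 0.06), and the centrosomal kinase NEK2 from 12.8 ± 0.494 to 4.68 ± 0.0544 (-1.44 ± 0.07). The histone gene HIST1H2AJ dropped from 603 ± 103 to 80.0 ± 5.67 FPKM (-3.07 ± 0.18). The lysosomal protease CTSB rose from 14.5 ± 0.363 to 56.1 ± 9.21 FPKM (1.70 ± 0.11), and KISS1, a metastasis suppressor, from 7.90 ± 0.749 to 46.1 ± 9.47 (2.23 ± 0.15). TPX2, KIF2C, NEK2, HIST1H2AJ, CTSB, KISS1 and the single genes given with the lists were called in 3 fits, with all groups pooled, with library weights and with the compared groups alone, a requirement chosen after seeing the data.

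Mitotic motors and kinases had a median of -1.03 (camera adjusted p = 5.41e-28, adjusted p = 0.0177 with an estimated correlation). In this list 42 of 43 fell, or 43 adjusted over the list alone, with 40 falling in all 3 fits. This call held with an estimated correlation, and the calls that follow were lost. Histone genes had a median of -1.62 (camera adjusted p = 7.99e-15, adjusted p = 0.234 with an estimated correlation). Of these, 29 of 35 fell, or 34 adjusted over the list alone, with 15 falling in all 3 fits. Centromere and kinetochore genes had a median of -0.44 (camera adjusted p = 8.02e-14, adjusted p = 0.0832 with an estimated correlation). Among them 35 of 45 fell, or 37 adjusted over the list alone, with 24 falling in all 3 fits. DNA replication genes had a median of -0.35 (camera adjusted p = 4.1e-12, adjusted p = 0.0832 with an estimated correlation). Of their members 33 of 45 fell, or 35 adjusted over the list alone, with 16 falling in all 3 fits. RRM2 changed by -1.52 ± 0.12 and GMNN, the inhibitor of repeated replication, by -0.99 ± 0.06. Lysosome and autophagy genes had a median of 0.32 (camera adjusted p = 1.01e-09, adjusted p = 0.0832 with an estimated correlation). In this list 20 of 34 rose, or 21 adjusted over the list alone, with 11 rising in all 3 fits. The protease CTSD rose by 1.30 ± 0.12 and the membrane protein LAMP1 by 1.09 ± 0.09. Extracellular matrix genes had a median of 0.30 (camera adjusted p = 0.000382, adjusted p = 0.195 with an estimated correlation). Of these, 15 of 26 rose and 3 fell, or 15 and 3 adjusted over the list alone, with 8 rising and 2 falling in all 3 fits. The collagen COL6A2 rose by 0.84 ± 0.07 and the protease MMP14 by 0.93 ± 0.10. Splicing factors had a median of -0.42 (camera adjusted p = 2.95e-07, adjusted p = 0.195 with an estimated correlation). Among them 20 of 35 fell and 1 rose, or 24 and 1 adjusted over the list alone, with 10 falling in all 3 fits. The splicing regulator TRA2B changed by -0.80 ± 0.10.

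Translation initiation factors had a median of -0.28 (camera adjusted p = 0.000397, adjusted p = 0.279 with an estimated correlation). Of their members 14 of 27 fell and 1 rose, or 15 and 1 adjusted over the list alone, with 3 falling in all 3 fits. The cap-binding protein EIF4E2 changed by -0.66 ± 0.09. ATF4 targets had a median of -0.20 (camera adjusted p = 0.00252, adjusted p = 0.421 with an estimated correlation). In this list 12 of 27 fell and 2 rose, or 16 and 4 adjusted over the list alone, with 4 falling in all 3 fits. ATF4 itself changed by -0.83 ± 0.12, the serine synthesis enzyme PHGDH by -0.79 ± 0.07 and asparagine synthetase ASNS by -0.68 ± 0.07. Mitochondrial ribosome genes had a median of -0.17 (camera adjusted p = 0.00226, adjusted p = 0.64 with an estimated correlation). Of these, 22 of 75 fell, or 22 adjusted over the list alone, with 6 falling in all 3 fits. That call was lost without IP CDK12 siRNA replicate 2, at -0.06. Oxidative phosphorylation genes had a median of -0.14 (camera adjusted p = 0.0332, adjusted p = 0.791 with an estimated correlation). Among them 17 of 71 fell, or 15 adjusted over the list alone, with 4 falling in all 3 fits. Their median turned to 0.05 without IP CDK12 siRNA replicate 2, and their call ended without control IP replicate 1 (-0.12), with library weights (-0.12) and with a pseudocount of 0.1 (-0.16). The filter at a mean FPKM of 5 ended the calls of initiation factors (-0.26), ATF4 targets (-0.19), the mitochondrial ribosome (-0.17) and oxidative phosphorylation (-0.16), and quantile normalization those of the mitochondrial ribosome (-0.06) and oxidative phosphorylation (-0.05). Ribosomal protein genes did not pass as a list (median -0.16, camera adjusted p = 0.0721). They passed without IP CDK12 siRNA replicate 3 (-0.48), control IP replicate 2 (-0.19) or 3 (-0.17), or rapamycin IP replicate 1 (-0.16) or 2 (-0.16). They also passed with the compared groups alone (-0.16), the length trend removed (-0.22), no scaling (-0.08) and no filter (-0.15). MYO1D rose from 2.96 ± 1.51 to 49.3 ± 28.7 FPKM (3.49 ± 0.41).

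With all groups pooled, 3174 genes changed in the IP, 1354 up and 1820 down, and 255 at least 2-fold. Library weights called 1105, the compared groups alone 1015, and all 3 fits shared 722, 291 up and 431 down. On data simulated with the wide spread of this IP pair, 53.1% of the pooled calls fell on unchanged genes and 0.978% of those shared by all 3 fits. Without scaling the pooled split was 2371 up and 976 down.

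The interaction of fraction and treatment asks whether an mRNA changed differently in the IP than in total RNA. After CDK12 siRNA, the lists of mitotic, DNA replication, homologous recombination, centromere and histone genes stood higher in the IP relative to total RNA. All 5 calls were lost, at adjusted p = 0.219, 0.219, 0.219, 0.457 and 0.59 with an estimated correlation. TOP2A changed by -1.17 in the IP and -2.99 in total RNA, an interaction of 1.82 ± 0.11 (adjusted p = 2.58e-05). HIST1H1E changed by -1.60 and -3.16, an interaction of 1.56 ± 0.17 (adjusted p = 0.000267). THBS1, a secreted matrix glycoprotein, dropped in total RNA from 32.7 ± 1.91 to 4.42 ± 0.317 FPKM. It measured 36.9 ± 2.17 and 35.3 ± 1.12 FPKM in the control and CDK12 siRNA IP, an interaction of 2.21 ± 0.16. Lower genes included the glycyl-tRNA synthetase GARS, an ATF4 target, at -1.75 ± 0.26 and EIF4G1, the scaffold itself, at -0.91 ± 0.16 (adjusted p = 0.00241).

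Mitotic motors and kinases had a median of 0.46 (camera adjusted p = 3.65e-08, adjusted p = 0.219 with an estimated correlation). Of their members 24 of 43 were higher, or 28 adjusted over the list alone, with 22 higher in all 3 fits. The spindle protein ASPM stood at 1.40 ± 0.10. DNA replication genes had a median of 0.46 (camera adjusted p = 5.86e-08, adjusted p = 0.219 with an estimated correlation). In this list 27 of 45 were higher and 2 lower, or 28 and 2 adjusted over the list alone, with 25 higher and 1 lower in all 3 fits. The licensing factors CDT1 and MCM4 stood at 1.22 ± 0.10 and 1.05 ± 0.09. Homologous recombination genes had a median of 0.43 (camera adjusted p = 1.9e-05, adjusted p = 0.219 with an estimated correlation). Of these, 16 of 21 were higher and 2 lower, or 16 and 2 adjusted over the list alone, with 15 higher and 1 lower in all 3 fits. BRCA1 stood at 0.66 ± 0.07 and BRIP1 at 0.92 ± 0.07. Histone genes had a median of 1.45 (camera adjusted p = 1.96e-05, adjusted p = 0.59 with an estimated correlation). Among them 19 of 35 were higher, or 22 adjusted over the list alone, with 14 higher in all 3 fits. Centromere genes had a median of 0.36 (camera adjusted p = 2.11e-05, adjusted p = 0.457 with an estimated correlation). Of their members 21 of 45 were higher and 2 lower, or 23 and 2 adjusted over the list alone, with 17 higher and 2 lower in all 3 fits. Extracellular matrix genes had a median of 0.40 (camera adjusted p = 7.22e-05, adjusted p = 0.242 with an estimated correlation). In this list 16 of 26 were higher and 1 lower, or 16 and 1 adjusted over the list alone, with 14 higher and 1 lower in all 3 fits. The fibronectin gene FN1 stood at 1.60 ± 0.13. Other cell cycle lists did not pass. Centrosome genes had a median of 0.14 (camera adjusted p = 0.0538), checkpoint genes of 0.24 (camera adjusted p = 0.117), cohesin genes of 0.23 (camera adjusted p = 0.0754) and the anaphase-promoting complex of -0.17 (camera adjusted p = 0.713). Centrosome and checkpoint genes passed with a pseudocount of 0.1 (0.32 and 0.41), quantile normalization (0.26 and 0.39), the length trend removed (0.15 and 0.24) and no filter (0.08 and 0.20). Centrosome genes also passed without scaling (0.12) and without IP CDK12 siRNA replicate 3 (0.18), control IP replicate 1 (0.14) or 2 (0.15), or total control replicate 1 (0.14). CHEK1 did not pass, at 0.15 (adjusted p = 0.245), and passed without scaling at 0.36 and with a pseudocount of 0.1 at 0.45.

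Translation initiation factors had a median of -0.44 (camera adjusted p = 0.00109, adjusted p = 0.502 with an estimated correlation). Of these, 15 of 27 were lower, or 16 adjusted over the list alone, with 10 lower in all 3 fits. EIF2S2 stood at -0.74 ± 0.11, EIF4E2 at -0.76 ± 0.13 and the cap-binding protein EIF4E at -0.77 ± 0.08. ATF4 targets had a median of -0.40 (camera adjusted p = 0.00167, adjusted p = 0.59 with an estimated correlation). Among them 17 of 27 were lower and 1 higher, or 18 and 1 adjusted over the list alone, with 11 lower and 1 higher in all 3 fits. The cystine transporter SLC7A11 stood at -0.76 ± 0.10. Heat shock genes had a median of -0.40 (camera adjusted p = 0.0191, adjusted p = 0.59 with an estimated correlation). Of their members 10 of 21 were lower and 1 higher, or 11 and 1 adjusted over the list alone, with 6 lower and 1 higher in all 3 fits. The chaperonin CCT5 stood at -1.12 ± 0.26 and HSPD1 at -0.66 ± 0.15, the latter not called without scaling (-0.28). Splicing factors had a median of -0.31 (camera adjusted p = 0.0146, adjusted p = 0.59 with an estimated correlation). In this list 12 of 35 were lower and 1 higher, or 12 and 1 adjusted over the list alone, with 8 lower and 1 higher in all 3 fits. Quantile normalization ended the calls of heat shock genes (-0.29) and splicing factors (-0.08), and the heat shock call ended among genes that overlap no other (-0.42). The splicing call also ended without scaling (-0.24), without IP CDK12 siRNA replicate 3 (-0.18) and at a mean FPKM of 5 (-0.29), where that of ATF4 targets ended too (-0.60).

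Ribosomal protein genes had a median of 0.01 relative to total RNA (camera adjusted p = 0.915), oxidative phosphorylation genes of -0.20 (camera adjusted p = 0.12), and p53 targets of -0.38 (camera adjusted p = 0.0641). None of these passed as a list, although p53 targets passed with the compared groups alone. Lists that passed in no comparison stood here at -0.14 for glycolysis, 0.14 for the interferon response, -0.11 for noncoding hosts of small nucleolar RNAs and 0.47 for nuclear and other untranslated RNAs. Polymerase II kinases stood at -0.46, the 5 epithelial markers tested at 0.18 and the 10 mesenchymal ones at 0.16. The interaction passed for 3881 genes, 1657 higher and 2224 lower, and for 2922 in all 3 fits, 1195 higher and 1727 lower. Without scaling the split was 3212 higher and 886 lower around a median of 0.19, and the count was 2585 or 2570 without total CDK12 siRNA replicate 1 or 2.

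**Figure D2:**
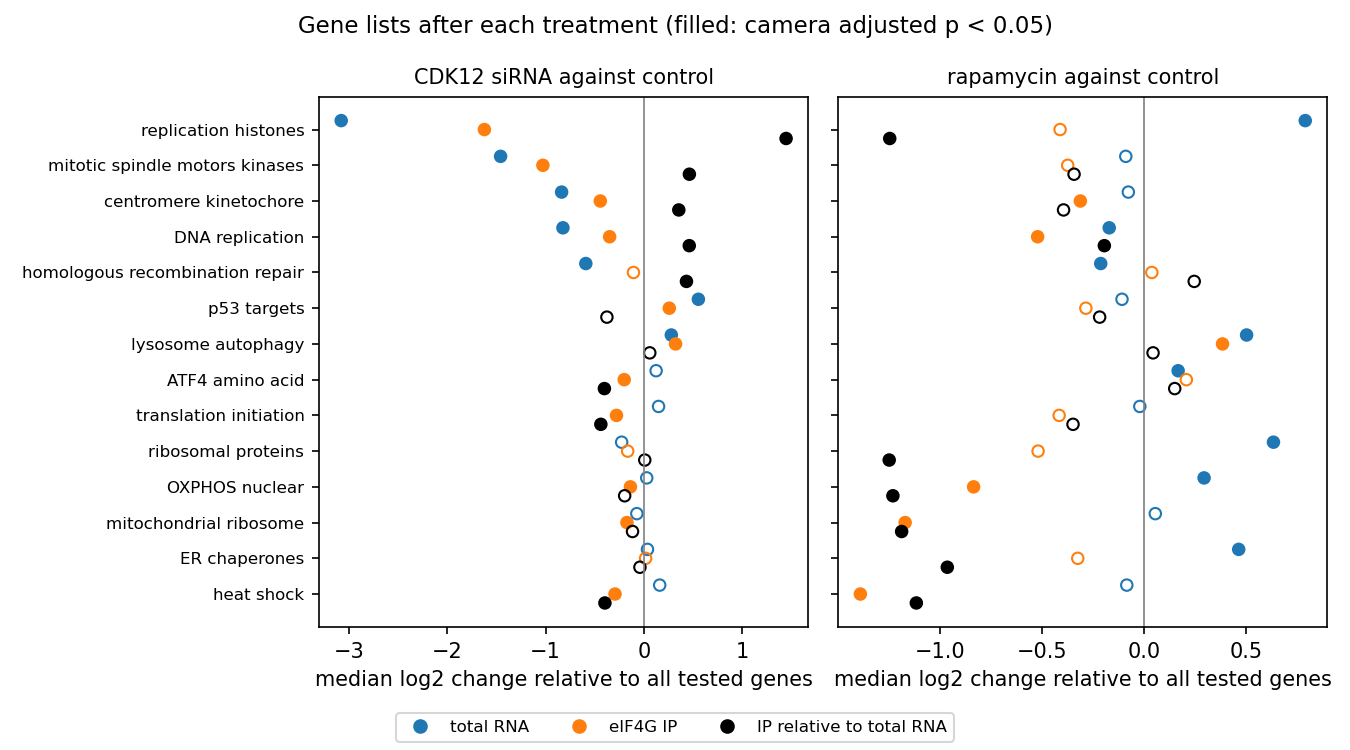
Median log2 change of 14 gene lists relative to all tested genes in total RNA (blue), the eIF4G IP (orange) and the IP relative to total RNA (black), after CDK12 siRNA (left) and with rapamycin (right), filled where camera passed at the preset correlation. Histones lay at -3.08 in total RNA and -1.62 in the IP after CDK12 siRNA, and ribosomal proteins at -1.25 in the IP relative to total RNA with rapamycin, a call that quantile normalization ended at -0.38. These 3 calls were lost, at adjusted p = 0.211, 0.234 and 0.712 with an estimated correlation.

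With rapamycin, the lists of lysosome genes, endoplasmic reticulum chaperones and ribosomal proteins stood higher in total RNA, where 37 of 77 ribosomal protein genes rose, or 42 adjusted over the list alone. These calls were lost, at adjusted p = 0.476, 0.476 and 0.59 with an estimated correlation. The autophagy receptor SQSTM1 rose from 8.37 ± 0.953 to 29.6 ± 2.09 FPKM (1.46 ± 0.11), and WIPI1, which acts in autophagosome formation, by 0.89 ± 0.05 (adjusted p = 1.51e-05). XBP1, a transcription factor of the unfolded protein response, rose from 4.90 ± 0.267 to 21.2 ± 3.10 FPKM (1.66 ± 0.16). DHRS2, a reductase, rose from 1.70 ± 0.218 to 26.6 ± 0.941 FPKM (3.10 ± 0.11, adjusted p = 1.95e-06). Tags summed over gene bodies also came to a larger share of depth in these libraries than in control total RNA, at 87.2% against 83.2%. Shorter genes rose more, with a rho of -0.42 between change and gene length across genes.

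Lysosome and autophagy genes had a median of 0.50 (camera adjusted p = 1.65e-08, adjusted p = 0.476 with an estimated correlation). Of these, 25 of 34 rose, or 26 adjusted over the list alone. Endoplasmic reticulum chaperones had a median of 0.46 (camera adjusted p = 1.65e-08, adjusted p = 0.476 with an estimated correlation). Among them 23 of 30 rose, or 24 adjusted over the list alone. HERPUD1, which acts in the disposal of misfolded proteins, rose by 1.05 ± 0.12. Ribosomal protein genes had a median of 0.64 (camera adjusted p = 3.85e-06, adjusted p = 0.59 with an estimated correlation). Of their members 37 of 77 rose, or 42 adjusted over the list alone. Histone genes had a median of 0.79 (camera adjusted p = 0.000364, adjusted p = 0.59 with an estimated correlation). In this list 18 of 35 rose and 1 fell, or 21 and 1 adjusted over the list alone. Oxidative phosphorylation genes had a median of 0.30 (camera adjusted p = 0.0102, adjusted p = 0.682 with an estimated correlation). Of these, 22 of 71 rose and 2 fell, or 22 and 2 adjusted over the list alone. ATP5B, of the ATP synthase, rose by 0.97 ± 0.15. Cholesterol synthesis genes had a median of 0.21 (camera adjusted p = 0.00338, adjusted p = 0.524 with an estimated correlation). Among them 14 of 29 rose and 2 fell, or 17 and 2 adjusted over the list alone. The feedback regulator INSIG1 rose by 1.04 ± 0.11. mTOR pathway genes had a median of 0.14 (camera adjusted p = 0.0141, adjusted p = 0.476 with an estimated correlation). Of their members 10 of 25 rose, or 10 adjusted over the list alone. The mTORC1 inhibitor DDIT4 rose by 0.99 ± 0.12 and the GTPase RRAGC by 0.96 ± 0.07. Cohesin and condensin genes had a median of -0.25 (camera adjusted p = 0.015, adjusted p = 0.524 with an estimated correlation). In this list 10 of 21 fell and 4 rose, or 11 and 5 adjusted over the list alone. The cohesin regulator PDS5B changed by -0.50 ± 0.05. The cohesin call was lost without total control replicate 2 (-0.21). MCM10, a replication initiation factor, changed by -0.60 ± 0.04.

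Rapamycin total RNA held 3632 changed genes, 2023 up and 1609 down, and 338 at least 2-fold, 278 of them up. Without scaling 5061 changed, 4160 up and 901 down around a median of 0.22, and with quantile normalization 5514, 2501 up and 3013 down. The count was 2290 or 2086 without total control replicate 1 or 2 and 1734 or 2273 without total rapamycin replicate 1 or 2. The filter at a mean FPKM of 5 ended the calls of oxidative phosphorylation (0.31), cholesterol (0.11) and mTOR pathway genes (0.52), and removal of the length trend ended that of cohesin genes (-0.08). Among genes that overlap no other, oxidative phosphorylation (0.20) and mTOR pathway genes (0.15) lost their calls.

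In the IP with rapamycin, mRNAs of mitochondrial proteins fell as a group and single ribosomal protein mRNAs fell steeply, while MYO1D and the RNA subunit of RNase P rose. The mitochondrial ribosome and oxidative phosphorylation calls were lost, at adjusted p = 0.71 and 0.734 with an estimated correlation. RPL26 dropped from 1031 ± 68.3 to 44.6 ± 11.1 FPKM (-4.83 ± 0.25, adjusted p = 3.13e-07). UQCRB, a subunit of respiratory complex III, dropped from 196 ± 5.95 to 8.25 ± 1.17 FPKM (-4.72 ± 0.22), and DBI from 576 ± 23.4 to 39.4 ± 8.69 (-4.16 ± 0.15). MYO1D rose from 2.96 ± 1.51 to 503 ± 48.9 FPKM (6.80 ± 0.41), and RPPH1, the RNase P RNA, from 959 ± 133 to 20329 ± 2672 (4.09 ± 0.14). The rapamycin IP also held fewer tags inside gene bodies than the control IP, at 92.4% against 97.0%.

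Mitochondrial ribosome genes had a median of -1.17 (camera adjusted p = 6.81e-08, adjusted p = 0.71 with an estimated correlation). Of these, 62 of 75 fell and 5 rose, or 62 and 5 adjusted over the list alone. MRPL32 changed by -3.70 ± 0.15. Oxidative phosphorylation genes had a median of -0.83 (camera adjusted p = 5.84e-05, adjusted p = 0.734 with an estimated correlation). Among them 52 of 71 fell and 6 rose, or 52 and 6 adjusted over the list alone. NDUFB3 changed by -3.23 ± 0.12. Heat shock genes had a median of -1.39 (camera adjusted p = 0.00252, adjusted p = 0.71 with an estimated correlation). Of their members 17 of 21 fell and 3 rose, or 17 and 3 adjusted over the list alone. The chaperonin TCP1 changed by -2.22 ± 0.14. DNA replication genes had a median of -0.52 (camera adjusted p = 0.00233, adjusted p = 0.71 with an estimated correlation). In this list 32 of 45 fell and 7 rose, or 33 and 7 adjusted over the list alone. GMNN changed by -1.89 ± 0.06 and CDT1, which GMNN inhibits, by 1.31 ± 0.06. Splicing factors had a median of -0.46 (camera adjusted p = 0.0347, adjusted p = 0.71 with an estimated correlation). Of these, 23 of 35 fell and 5 rose, or 23 and 5 adjusted over the list alone. SRSF3 changed by -2.03 ± 0.14. The splicing call was lost without rapamycin IP replicate 1 (-0.44), with the length trend removed (-0.40) and with protein-coding genes only (-0.42). Lysosome and autophagy genes had a median of 0.39 (camera adjusted p = 0.00549, adjusted p = 0.71 with an estimated correlation). Among them 21 of 34 rose and 7 fell, or 21 and 7 adjusted over the list alone. NPC1 rose by 1.13 ± 0.04 and the glycogen-degrading enzyme GAA by 1.01 ± 0.06, whereas the protease CTSL changed by -3.21 ± 0.20. Ribosomal protein genes did not pass as a list (median -0.52, camera adjusted p = 0.0596), although 38 of 77 fell and 13 rose, or 37 and 13 adjusted over the list alone. They passed without control IP replicate 2 (-0.56) or rapamycin IP replicate 1 (-0.61) and with no filter (-0.54).

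Of all tested genes 7184 changed, 3195 up and 3989 down, and 1969 at least 2-fold, 1503 of them down. Without scaling the split was 4235 up and 3106 down (median 0.12), where ribosomal proteins passed at -0.38. Quantile normalization ended the calls of heat shock genes (-0.32) and splicing factors (-0.08). The filter at a mean FPKM of 5 ended the calls of oxidative phosphorylation (-0.14), heat shock (-0.69), DNA replication (-0.82), splicing (-0.19) and lysosome genes (0.87), and the heat shock call ended among genes that overlap no other (-1.10).

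Relative to total RNA, mRNAs that the control IP enriched were lower in the rapamycin IP. RPL26 changed by -4.83 in the IP while its total RNA difference of -0.51 did not pass, and the interaction was -4.32 ± 0.37 (adjusted p = 1.98e-05). DBI stood at -4.20 ± 0.22 and NDUFB3 at -3.45 ± 0.18. MANF, a secreted factor of the endoplasmic reticulum stress response, stood at -3.48 ± 0.17, and the mitochondrial co-chaperone HSPE1 at -3.26 ± 0.26. MYO1D stood at 5.82 ± 0.60, and MTOR at 0.42 ± 0.06, which removal of the length trend reduced to 0.07 and ended.

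Oxidative phosphorylation genes had a median of -1.23 (camera adjusted p = 3.26e-08, adjusted p = 0.712 with an estimated correlation). Of their members 61 of 71 were lower and 2 higher, or 63 and 2 adjusted over the list alone. Mitochondrial ribosome genes had a median of -1.19 (camera adjusted p = 7.12e-09, adjusted p = 0.712 with an estimated correlation). In this list 64 of 75 were lower and 3 higher, or 64 and 3 adjusted over the list alone. Ribosomal protein genes had a median of -1.25 (camera adjusted p = 1.96e-05, adjusted p = 0.712 with an estimated correlation). Of these, 49 of 77 were lower and 3 higher, or 49 and 3 adjusted over the list alone. Endoplasmic reticulum chaperones had a median of -0.96 (camera adjusted p = 8.73e-05, adjusted p = 0.712 with an estimated correlation). Among them 25 of 30 were lower and 1 higher, or 25 and 1 adjusted over the list alone. The disulfide isomerase PDIA6 stood at -2.14 ± 0.13. Histone genes had a median of -1.25 (camera adjusted p = 0.00261, adjusted p = 0.712 with an estimated correlation). Of their members 22 of 35 were lower, or 23 adjusted over the list alone. HIST1H1E stood at -1.97 ± 0.17. Heat shock genes had a median of -1.12 (camera adjusted p = 0.00279, adjusted p = 0.712 with an estimated correlation). In this list 15 of 21 were lower, or 15 adjusted over the list alone. The chaperonin CCT8 stood at -1.90 ± 0.16. DNA replication genes had a median of -0.19 (camera adjusted p = 0.0277, adjusted p = 0.712 with an estimated correlation). Of these, 25 of 45 were lower and 3 higher, or 25 and 3 adjusted over the list alone. GMNN stood at -1.38 ± 0.08. The proliferation marker MKI67, low in the control IP, moved the other way (1.72 ± 0.18), as did CASC5, a kinetochore scaffold (0.66 ± 0.05). Initiation factors (median -0.35, camera adjusted p = 0.0799) and the other oligopyrimidine mRNAs (median -0.18, camera adjusted p = 0.151) did not pass as lists.

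The interaction passed for 6176 genes, 2423 higher and 3753 lower around a median of -0.14, and 1714 of the 1949 that differed at least 2-fold were lower. Quantile normalization gave 2832 higher and 2583 lower (median 0.02) and ended the calls of ribosomal proteins (-0.38), histones (-0.10), heat shock (-0.16) and DNA replication genes (-0.12). A filter at a mean FPKM of 5 ended the calls of oxidative phosphorylation (-0.76), ribosomal proteins (-0.66), endoplasmic reticulum chaperones (-0.21), histones (-0.45), heat shock (-0.35) and DNA replication genes (-0.35). Among genes that overlap no other, heat shock (-0.68) and DNA replication genes (-0.14) lost their calls, the latter also with protein-coding genes only (-0.16).

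**Figure D3:**
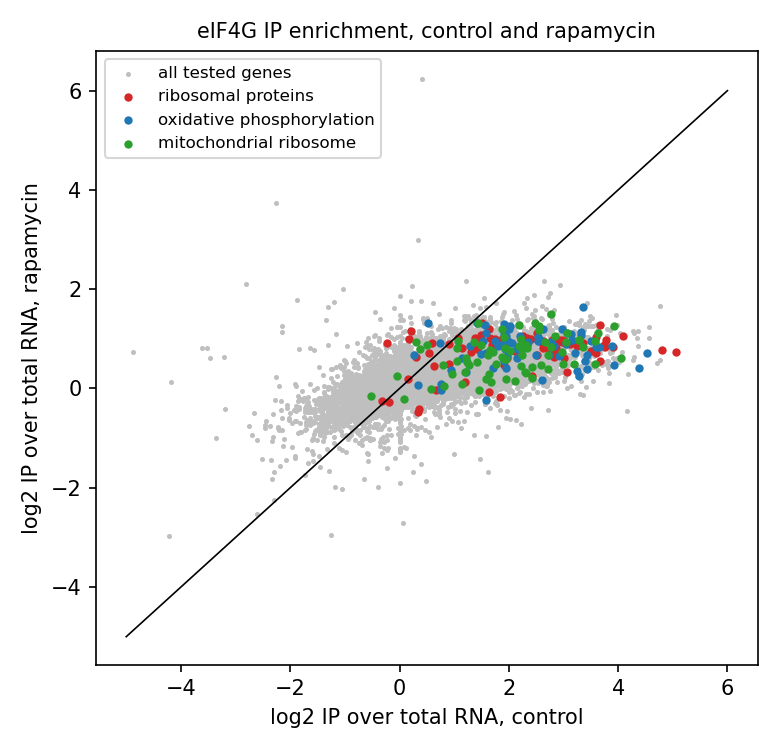
log2 ratio of eIF4G IP over total RNA per tested gene in control cells (x axis) and with rapamycin (y axis), on scaled log2(FPKM + 1), with all tested genes in grey, 3 lists in colour and the line of equality in black. Most genes of the 3 lists lie below the line, with median changes of -1.25 for ribosomal proteins, -1.23 for oxidative phosphorylation and -1.19 for the mitochondrial ribosome, and quantile normalization moved the ribosomal proteins to -0.38 and ended their call. All 3 calls were lost, at adjusted p = 0.712 with an estimated correlation.

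CDK12 siRNA was then set against rapamycin, as the change of the IP relative to total RNA. HMGB2, a chromatin protein of dividing cells, stood 4.96 ± 0.20 higher after CDK12 siRNA than with rapamycin (adjusted p = 9.11e-07), the mitotic kinase CDK1 2.68 ± 0.23 and HIST1H1E 3.53 ± 0.18. On the lower side, ASNS stood at -1.62 ± 0.12, PHGDH at -1.33 ± 0.11, SLC7A11 at -1.45 ± 0.10 and EIF4G1 at -1.30 ± 0.17. Histone genes had a median of 2.51 (camera adjusted p = 1.43e-05, adjusted p = 0.752 with an estimated correlation). Among them 29 of 35 were higher, or 29 adjusted over the list alone. Ribosomal protein genes had a median of 1.15 (camera adjusted p = 5.96e-05, adjusted p = 0.834 with an estimated correlation). Of their members 53 of 77 were higher and 1 lower, or 53 and 1 adjusted over the list alone. Oxidative phosphorylation genes had a median of 0.91 (camera adjusted p = 3.28e-06, adjusted p = 0.834 with an estimated correlation). In this list 60 of 71 were higher and 2 lower, or 60 and 2 adjusted over the list alone. Mitochondrial ribosome genes had a median of 0.91 (camera adjusted p = 1.07e-06, adjusted p = 0.752 with an estimated correlation). Of these, 64 of 75 were higher and 3 lower, or 64 and 3 adjusted over the list alone. Mitotic motors and kinases had a median of 0.56 (camera adjusted p = 6.34e-05, adjusted p = 0.752 with an estimated correlation). Among them 33 of 43 were higher and 3 lower, or 33 and 3 adjusted over the list alone. ATF4 targets had a median of -0.53 (camera adjusted p = 0.00211, adjusted p = 0.752 with an estimated correlation). Of their members 14 of 27 were lower and 2 higher, or 14 and 2 adjusted over the list alone. DNA replication genes had a median of 0.53 (camera adjusted p = 1.07e-06, adjusted p = 0.752 with an estimated correlation), centromere genes of 0.56 (camera adjusted p = 0.00022, adjusted p = 0.752 with an estimated correlation).

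The difference passed for 6383 genes, 3958 higher and 2425 lower after CDK12 siRNA around a median of 0.21. Without scaling the split was 5036 and 1751 (median 0.40) and with quantile normalization 3093 and 3177 (median 0.01). The filter at a mean FPKM of 5 ended the calls of ribosomal proteins (0.57), oxidative phosphorylation (0.43), mitotic (0.64) and centromere genes (0.63). Since the rapamycin libraries alone carry their date code, date is part of this difference.

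Across genes, the changes of the IP relative to total RNA after the 2 treatments correlated weakly, with r = 0.22 and Spearman's rho = 0.18. Unchanged groups simulated against the same controls gave r = 0.46 on average, with a covariance of 0.0274 against the 0.106 observed, a difference of 0.0786. Both treatments lowered 984 genes and raised 572, against 842 and 405 for independent lists, and 1071 moved in opposite directions against 1172. In the IP itself r was 0.57 (simulated 0.40, covariance 0.205 against a simulated 0.0109), with 1352 genes lower in both and 859 higher in both against 733 and 437 for independent lists. In total RNA r was 0.04 (simulated 0.50, covariance 0.00879 against a simulated 0.0165). The controls were not split between the treatments, so noise of the shared controls beyond that simulated may add to any excess.

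The authors' deposited table marks 1114 genes as losing eIF4G binding after CDK12 siRNA and 3285 after rapamycin. Of the 888 genes marked in the authors' deposited table for CDK12 that were tested, the interaction called 724 lower and left 164 uncalled. Of the 3137 tested genes marked for rapamycin in the authors' deposited table, it called 2890 lower and left 247 uncalled. Narrower sets in the authors' deposited table, of only binding, hold 1001 genes for CDK12 and 2961 for mTOR. The 391 genes shared by these narrower sets of the authors' deposited table, 366 of them tested, held 5 of 21 heat shock genes (0.776 by chance, Fisher's exact test over 32 lists, two-sided adjusted p = 0.0183). They held 9 of 71 oxidative phosphorylation genes in the authors' deposited table (2.62 by chance, adjusted p = 0.0183). In the same set of the authors' deposited table, 5 of 77 ribosomal protein genes (2.84 by chance, adjusted p = 0.838) and 8 of 75 mitochondrial ribosome genes (2.77 by chance, adjusted p = 0.0667) did not pass. Those marks came from these same libraries, so they are no independent evidence of direction.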

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

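The tests of ribosomal protein mRNAs against other enriched mRNAs, of histone genes, of MYO1D in total RNA and of nuclear RNA were chosen only after the result was seen.

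With rapamycin, IP and total RNA changed differently for 6176 genes, and the oxidative phosphorylation list stood at -1.23 in the IP relative to total RNA. Gene length is argued against as the whole cause. The ribosomal protein, oxidative phosphorylation and mitochondrial ribosome lists hold 223 genes. Their median was -0.99 with the length trend removed (95% interval -1.18 to -0.91, against -1.21 before). All 3 lists still passed at the preset correlation. Before removal their calls were lost at adjusted p = 0.712 with an estimated correlation. Intron content was not tested. A dilution of the rapamycin IP with unselected RNA, or a poorer selection, may account for part or all of the loss. Of 2505 protein-coding genes at least 2-fold enriched in the control IP, 2222 were lower and 2 higher, or 0.0798% (exact interval 0.00967 to 0.288). Retained enrichment had quartiles of 8.62 and 30.7%. The spread expected from noise was not computed, so this cannot tell whether dilution had a single share. A loss of ribosomal protein mRNAs beyond other enriched mRNAs stayed undecided, because they retained 14.5% and the other enriched genes 17.2%, a difference of -2.78 points (interval -5.17 to 3.10). An action of rapamycin on eIF4G complexes was not tested apart from these, and date, dilution and drug cannot be told apart because the rapamycin libraries alone carry their date code.

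After CDK12 siRNA, IP and total RNA changed differently for 3881 genes, and the mitotic, DNA replication, centromere and histone lists stood higher in the IP relative to total RNA, calls lost at adjusted p = 0.219, 0.219, 0.457 and 0.59 with an estimated correlation. For the 35 histone genes, which have no introns, intron reads of pre-mRNA are argued against (median interaction 1.45, 95% interval 0.88 to 1.69). The 57 shortest cell cycle genes (at most 19301 bp) stood at 0.57 (0.34 to 0.71), the 56 longest at 0.32 (0.16 to 0.48). Both can hold introns, so such reads stay open there. A weaker knockdown in the cells used for the IP could give the same pattern and stays open, since CDK12 itself fell less in the IP (0.521 to 0.416 FPKM) than in total RNA (1.68 to 0.707 FPKM), an interaction of 0.38 ± 0.07 (adjusted p = 0.00367), but is low in the IP, and nothing ties an IP library to a total RNA library. A slower loss of mRNA held in eIF4G complexes is a hypothesis that stays open and untested.

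MYO1D (hg19 chromosome 17, 31086830 to 31204191) rose in the IP by 3.49 ± 0.41 after CDK12 siRNA and 6.80 ± 0.41 with rapamycin. More MYO1D RNA in the cells is argued against as the whole cause, since total RNA differed by 0.98 with rapamycin (95% interval -0.02 to 1.99) and by 0.27 after CDK12 siRNA (-0.73 to 1.27), below the IP intervals of 5.89 to 7.72 and 2.57 to 4.40. A general rise of untranslated RNA stays open. The 15 nuclear and other such RNAs had a median of 0.22 (-0.26 to 0.46) in the CDK12 siRNA IP. In the rapamycin IP it was 1.33 (-0.13 to 1.83), and the member RPPH1 rose by 4.09 ± 0.14. MYO1D was picked for its rise, so a median below it decides nothing. UNC45B, on the same chromosome (33475283 to 33516364), rose by 4.97 ± 0.44 in the rapamycin IP, while the highest of the 21 genes between them, CCL2, measured 27.1 FPKM there. A short sequence inside the gene body stays open as a source, because a table of gene values holds no positions within a gene.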

How the results depend on the processing

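The tests on protein-coding genes, on genes without overlaps and with the length trend removed were chosen only after the result was seen. Over all alternatives, list results kept direction and side of the threshold 2451 times, lost their call 105 times, gained one 51 times and reversed 8 times, and named genes did so 13898, 214, 34 and 5 times. Counts of changed genes moved by over 1.5 times under the settings given here, and the cause was not tested unless stated. Without a filter more genes were tested, and 10790 changed in the IP and 6344 in total RNA with rapamycin, 8702 in total RNA after CDK12 siRNA, 7151 and 9474 in the interactions with CDK12 siRNA and rapamycin, 14028 between IP and total RNA and 10720 between the treatments, with 146 list calls. With the filter at a mean FPKM of 5 fewer genes were tested, and the counts were 846 in the IP and 732 in total RNA after CDK12 siRNA, 1716 in the IP and 795 in total RNA with rapamycin, 746 and 1646 for the interactions, 1973 between IP and total RNA and 1653 between the treatments, with 43 list calls. Quantile normalization called 5514 genes in total RNA with rapamycin, the compared groups alone 1015 in the IP after CDK12 siRNA, and library weights 1105 there and 5815 in total RNA with rapamycin. Camera with estimated correlations made 7 list calls and fry, which does not compare a list with other genes, 178, against 87. The correlation of 0.22 between the interactions across genes was 0.293 with the stricter filter, 0.145 with quantile normalization, 0.162 without scaling and 0.292 with the length trend removed, against an SD of 0.0289 over fits without 1 library.

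Without 1 library at a time, the lone library of a group being assumed to vary like the other groups, the counts ran from 2541 to 4128 in the IP after CDK12 siRNA, 6252 to 7576 in the IP with rapamycin, 2745 to 4928 in total RNA after CDK12 siRNA, 1734 to 4611 in total RNA with rapamycin, 2570 to 4910 and 5225 to 6733 for the interactions, 7373 to 8169 between IP and total RNA and 5564 to 6818 between the treatments. List calls ran from 85 to 95 and the correlation from 0.164 to 0.270. The libraries that moved a count by over 1.5 times were replicates 1 and 2 of total RNA in each condition, as given with the results.

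Directions reversed, the cause not tested, for centromere genes in the rapamycin IP (0.375), and between IP and total RNA for ATF4 targets (-0.366), endoplasmic reticulum chaperones (-0.222), other oligopyrimidine mRNAs (-0.268) and initiation factors (-0.181), all with the stricter filter. Quantile normalization reversed other oligopyrimidine mRNAs (-0.374) and initiation factors (-0.0134) between IP and total RNA and RPL11 in the IP after CDK12 siRNA (0.0448). Oxidative phosphorylation in the IP after CDK12 siRNA reversed without IP CDK12 siRNA replicate 2 (0.0525), and was lowest without replicate 3 (-0.378). Removal of the length trend reversed CDK13 in the rapamycin interaction (-0.0109), STAG1 between IP and total RNA (0.239), and MTOR (0.152) and CDK12 (0.0194) between the treatments.

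Replicate numbers did not pair the libraries: deviations of the 12 same-number pairs correlated between -0.112 and 0.0962, and 0 pairs passed 0.1. With the number as a replicate block, 2931 genes changed in the IP after CDK12 siRNA, 7111 in the IP with rapamycin, 4264 and 3651 in total RNA, 3792 and 6112 in the interactions, 7889 between IP and total RNA and 6265 between the treatments, with 89 list calls and a correlation of 0.213. With date code and number as the replicate block, the interactions called 3554 and 5913 genes and the difference of treatments 6048. Depth limits changes of genes near 1 FPKM, which the log2(FPKM + 1) scale understates.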

Other observations

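After CDK12 siRNA, EIF4E, the cap-binding protein, rose in total RNA by 0.40 ± 0.06 and fell in the IP by 0.37 ± 0.05. EIF4G1 rose in total RNA by 0.47 ± 0.12 (adjusted p = 0.0105). EIF4EBP1, the repressor of EIF4E that mTORC1 phosphorylates, passed in neither fraction, at 0.04 in total RNA and -0.24 in the IP. The total RNA call of EIF4G1 was lost without scaling (0.26), without total CDK12 siRNA replicate 1 (0.47) or 2 (0.48) and without total control replicate 2 (0.44). Its IP change of -0.44 was called with all groups pooled and not in all 3 fits. The IP call of EIF4EBP1 was gained without IP CDK12 siRNA replicate 3 (-0.32), control IP replicate 2 (-0.30) or rapamycin IP replicate 1 (-0.23) or 2 (-0.23). It was also gained with protein-coding genes only (-0.24) and among genes that overlap no other (-0.24). With rapamycin, MTOR rose in the IP by 0.51 ± 0.04 (0.28 with quantile normalization, 1.38 with a pseudocount of 0.1), with a total RNA difference of 0.09 that did not pass. That difference passed without scaling (0.21), with the length trend removed (0.32) and with library weights (0.09). EIF4E fell by 0.87 ± 0.05 in the IP and 0.45 ± 0.06 in total RNA, and CHEK1 fell by 0.54 ± 0.07 in the IP.

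Further lists passed in the IP after CDK12 siRNA, all lost with an estimated correlation. DNA damage checkpoint genes had a median of -0.22 (camera adjusted p = 0.000836, adjusted p = 0.0832 with an estimated correlation). Of these, 12 of 19 fell, or 12 adjusted over the list alone, with 4 falling in all 3 fits. Cohesin genes had a median of -0.28 (camera adjusted p = 4.45e-05, adjusted p = 0.195 with an estimated correlation). Among them 13 of 21 fell, or 15 adjusted over the list alone, with 4 falling in all 3 fits. Centrosome genes had a median of -0.16 (camera adjusted p = 4.99e-05, adjusted p = 0.0735 with an estimated correlation). Of their members 13 of 36 fell, or 17 adjusted over the list alone, with 6 falling in all 3 fits. Cytoskeleton genes had a median of -0.31 (camera adjusted p = 0.000911, adjusted p = 0.359 with an estimated correlation). In this list 14 of 30 fell and 1 rose, or 15 and 1 adjusted over the list alone, with 7 falling in all 3 fits. The tubulin TUBA4A changed by -1.60 ± 0.15. Targets of p53 had a median of 0.26 (camera adjusted p = 0.000911, adjusted p = 0.279 with an estimated correlation). Of these, 11 of 25 rose and 2 fell, or 14 and 2 adjusted over the list alone, with 3 rising and 1 falling in all 3 fits. The cell death gene BBC3 rose by 1.04 ± 0.10. Immediate early genes had a median of 0.28 (camera adjusted p = 0.0059, adjusted p = 0.279 with an estimated correlation). Among them 6 of 17 rose and 1 fell, or 7 and 1 adjusted over the list alone, with 3 rising in all 3 fits. JUNB rose by 1.07 ± 0.15. The immediate early call was lost without IP CDK12 siRNA replicate 2 (0.22). Heat shock genes had a median of -0.29 (camera adjusted p = 0.00664, adjusted p = 0.421 with an estimated correlation). Of their members 9 of 21 fell and 1 rose, or 11 and 1 adjusted over the list alone, with 1 falling in all 3 fits. This call was lost without IP CDK12 siRNA replicate 3 (-0.21), with quantile normalization (-0.04) and at a mean FPKM of 5 (-0.21). Genes of the anaphase-promoting complex had a median of -0.22 (camera adjusted p = 0.0223, adjusted p = 0.341 with an estimated correlation). In this list 7 of 12 fell, or 7 adjusted over the list alone, with 2 falling in all 3 fits. Their call was lost without IP CDK12 siRNA replicate 2 (-0.25).

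Of the enrichment over total RNA that protein-coding genes at least 2-fold enriched in the control IP had, the rapamycin IP retained a median of 50.1% for 6 extracellular matrix genes, 48.5% for 12 ATF4 targets and 44.2% for 8 immediate early genes, and 2.47% for 10 cholesterol synthesis genes, 5.80% for 12 splicing factors and 7.63% for 13 centromere genes. These shares were computed after the loss was seen, from the control values used to choose genes, and list differences were not tested. Of 20 haematopoietic marker genes 0 reached the filter, with a highest group mean of 0.87 FPKM, and of 13 mitochondrially encoded genes 0 were in the table.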
